A study of Mus musculus with 4 samples.

How the data were processed

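The series used single-nucleus ATAC-seq, in which a transposase cuts DNA where chromatin is open, to profile intestinal epithelium of mice on either of 2 purified diets. AIN is a balanced control diet, and NWD1 is a Western-style diet with more fat and less calcium, vitamin D, methyl donors and fibre. Per the labels, B6 mice were fed for 3 months after weaning, Epcam-positive and Cd45-negative cells were sorted, and libraries were made with the 10x Chromium kit. Each diet has 2 libraries, A and B. Nothing in the labels says that the libraries of a diet are separate animals, so p-values measure the spread between these samples.

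The submitters' processing notes name Cell Ranger ATAC 2.1.0 and the mm10 genome, without settings. For each library the deposited lists of peaks hold intervals without a height or score, and the deposited barcode lists hold 1 cell barcode per line. Peaks were called by the authors separately in each library, as the lists differ in number and bounds. The deposited matrix of NWD1 A holds raw counts per peak and barcode. As in counts of both fragment ends, even values outnumber odd ones, with 4445090 odd among 34988194 entries. Whether Cell Ranger counted fragments or cut sites is not stated. The matrices of AIN A, AIN B and NWD1 B were not analysed here. The diets are therefore compared by where peaks were called, and cell types are described in NWD1 A alone. A list of calls turns a graded signal into presence or absence, so a region near the calling limit can differ between lists with little change in signal, and a deeper library can call more. Widths also vary little between peaks, so a gene's covered length moves in steps of about 1 peak.

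Peaks on the standard chromosomes were merged into union regions where they overlapped or touched, and a region counted as present in a library with any overlapping peak. Diet-specific regions had a peak in both libraries of a diet and in neither of the other. The same was counted for the other 2 splits of the 4 libraries, by replicate letter (A against B) and crossed (AIN A with NWD1 B). Genes came from an annotation of the same build, with 21883 protein-coding genes matched by symbol and all 385 genes of the fixed lists found. It gives gene bounds without strand, exons or introns. A gene locus is therefore the gene body with 2 kb at both ends, a gene-end peak lies within 1 kb of either end, and the wider alternatives take 5 kb or 10 kb around either end. Region and covered-length code was checked base by base on 20 simulated list sets, with 0 of 16000 windows wrong.

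Library values were compared by two-sided exact permutation tests. With 2 libraries against 2 there are 6 arrangements, and the smallest p they allow is 0.333. Accessible length, the bp of a gene locus covered by peaks, was divided by the covered Mb of the library, and log2 values with a pseudocount of 1 were fitted in limma 3.58.1 (R 4.3.3) with trend and robust variance, for genes with length in at least 2 libraries. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The 29 gene lists were tested with camera (preset correlation 0.01), with an estimated correlation, and with fry. On simulated changes the gene test recovered 3 of 100 genes at a log2 change of 1 and 51 of 100 at 2, with 2 false calls, so smaller changes are mostly beyond its reach. Fisher's exact test compared list membership between AIN-only and NWD1-only genes and regions.

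In NWD1 A, barcodes with at least 1000 counts and fewer than 30895 (5 times the median) were kept. Binarized counts were weighted by term frequency and inverse document frequency and reduced to components. The first component was dropped for its correlation of 0.974 with depth, and the next 30 were used. Nuclei were clustered with Leiden at resolution 0.8 on 20 neighbours (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, scikit-learn 1.9.0). A cluster took the name of a fixed marker list when at least 4 of the list's genes were among its 200 genes of highest fold and the list's median log2 fold over detected genes was above 0.4. That naming rule was set after the clusters were seen. Scrublet called 1 of 8884 nuclei a doublet, so the caller was taken not to have worked, and doublets remain among the nuclei. On a simulated matrix with 12 clusters, 13 were found with an adjusted Rand index of 0.966. Shares of nuclei have exact Clopper-Pearson 95% intervals, which cover counting error only.

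The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes 12 genes per direction past the threshold or, where fewer pass, of smallest p among genes whose diets do not overlap. It adds 3 genes of smallest p per list, the 5 widest regions and gene-end peaks per direction, the 10 genes of highest fold per cluster, and Lgr5, Bmi1, Ascl2, Olfm4, Hnf4a, Vdr and Cyp24a1. Some genes that the rule takes are not reported here. Alternatives varied the pseudocount, filter, scaling, gene window, peak width, list length, overlap, limma settings, replicate block, left-out library and cluster settings. Thinning lists at random, region recovery by cluster, neighbouring regions, cluster gene sets and region counts by list were added after the data had been seen. The motif comparison was not run, since the genome sequence was not used here. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.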

Results

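Open chromatin was mapped in single nuclei of mouse intestinal epithelium after 3 months on the AIN control diet (2 libraries) or the NWD1 Western-style diet (2 libraries). The series concerns how diet alters the epigenetic state of intestinal epithelial cells, including the return of Bmi1-positive cells to a stem cell state. AIN A held 13324 barcodes and 169224 peaks on the standard chromosomes, and AIN B held 9148 barcodes and 160653 peaks. NWD1 A held 9379 barcodes and 152715 peaks, and NWD1 B held 9934 barcodes and 156488 peaks. Counts per nucleus were used for NWD1 A alone, which had 76310330 counts in peaks and a median of 6179 per barcode. Coordinates are on mm10, and the annotation used gives gene bounds, so positions within a gene are not divided into exons and introns.

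**Figure D1:**
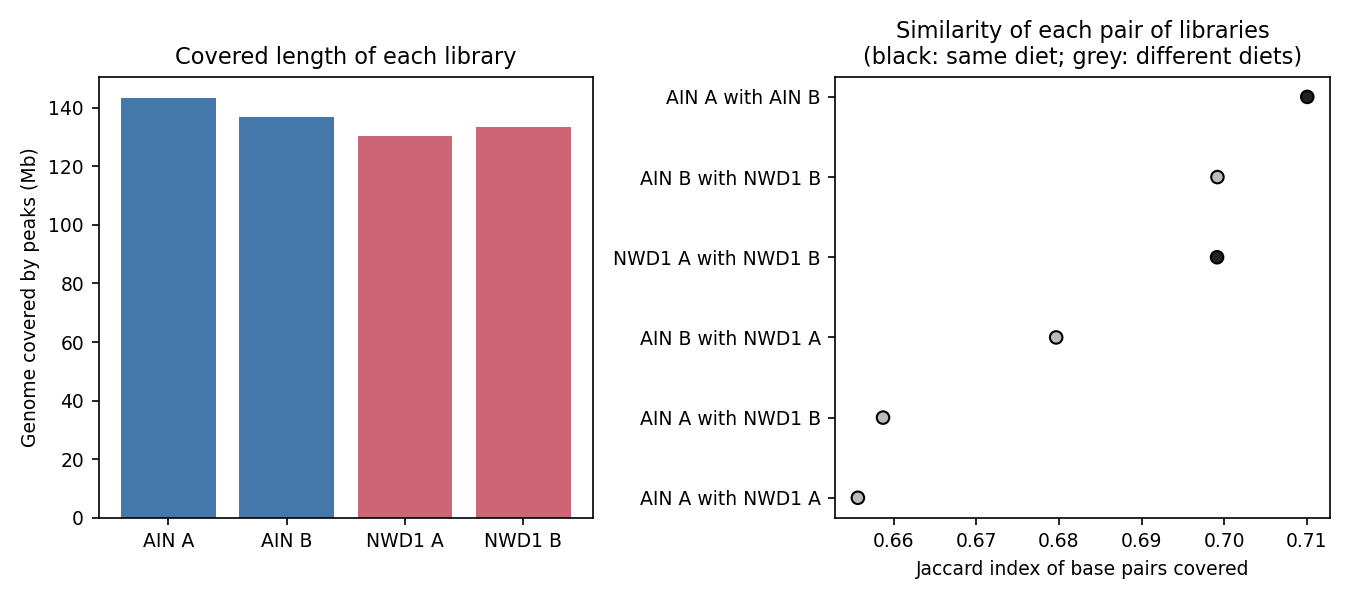
Genome covered by peaks in each library, in Mb (bars, left), and Jaccard index of the base pairs covered for each pair of libraries (points, right, black within a diet and grey across diets). AIN libraries cover a mean of 140.1 Mb and NWD1 libraries 131.9 Mb, and the pairs range from 0.656 to 0.710.

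The first comparison asks whether the diets differed in how much chromatin was called open. Peaks numbered 164938 ± 6061 in AIN and 154602 ± 2668 in NWD1 (SD, n = 2 each), a difference of -10337, and covered 140.1 ± 4.60 Mb and 131.9 ± 2.05 Mb. Peaks within 1 kb of a gene end made up 12.6% ± 0.204 of the AIN lists and 12.9% ± 0.150 of the NWD1 lists (SD, n = 2 each). The median peak was 877 bp wide in AIN and 878 bp in NWD1. Both AIN libraries lay above both NWD1 libraries in peak number, and the two-sided exact permutation p was 0.333 for peak number, covered length and gene-end share, the smallest that this design allows. AIN A also held the most barcodes, with diet means of 11236 ± 2953 and 9656.5 ± 392 barcodes (SD, n = 2 each, exact permutation p = 1), and without AIN A the difference in peak number was -6051.5.

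The second comparison asks whether libraries of a diet opened the same regions. The lists of AIN A and AIN B shared 0.710 of their covered bp (Jaccard index), and those of NWD1 A and NWD1 B shared 0.699. Pairs across diets shared between 0.656 (AIN A with NWD1 A) and 0.699 (AIN B with NWD1 B). The mean within a diet exceeded the mean across diets by 0.0313, against -0.00947 for the split by replicate letter and -0.0218 for the crossed split, and without AIN A it did so by 0.00972. Among 210129 union regions, 117956 (56.1%) were called in all 4 libraries, 8684 in AIN only and 4063 in NWD1 only. The 12747 diet-specific regions compare with 7061 for the split by letter and 5373 for the crossed split, though 3 splits cannot give a share under 0.05.

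Diet-specific regions lay mostly away from gene ends. Within 1 kb of a gene end lay 6.70% of AIN-only regions, 5.56% of NWD1-only regions and 15.2% of regions called in all 4 libraries. For all union regions, which include the latter, the share was 11.2%, so regions called in fewer libraries also lay below 15.2% as a whole. Regions of the other splits were not placed in this way, so the low share cannot be tied to diet. The widest NWD1-only region, at chromosome 5, 145992933 to 145994763 (1831 bp), lay inside Cyp3a25, a cytochrome P450 gene. The next, at chromosome 10, 89491096 to 89492886 (1791 bp), lay inside Nr1h4, which encodes the bile acid receptor FXR. The others were inside Urb2 (chromosome 8, 124023518 to 124025277), inside the potassium channel gene Kcnj15 (chromosome 16, 95268936 to 95270578), and 373026 bp from Bckdhb (chromosome 9, 84497267 to 84498965). The widest AIN-only region, at chromosome 13, 77169626 to 77171760 (2135 bp), lay inside 2210408I21Rik. The next lay inside the transcription factor gene Zeb2 (chromosome 2, 45044509 to 45046396, 1888 bp) and inside Fubp1 (chromosome 3, 152221681 to 152223550). The last of the 5 AIN-only regions were 4395 bp from Ust (chromosome 10, 8198561 to 8200357) and inside Lrrd1 (chromosome 5, 3866226 to 3867966). In lists of equal size, made by keeping the widest peaks, NWD1-only regions numbered 6753. Leaving out AIN A, AIN B, NWD1 A or NWD1 B gave 25886, 34085, 28208 or 30309 diet-specific regions, since the diet with 1 library left then needed a peak in that library alone.

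**Figure D2:**
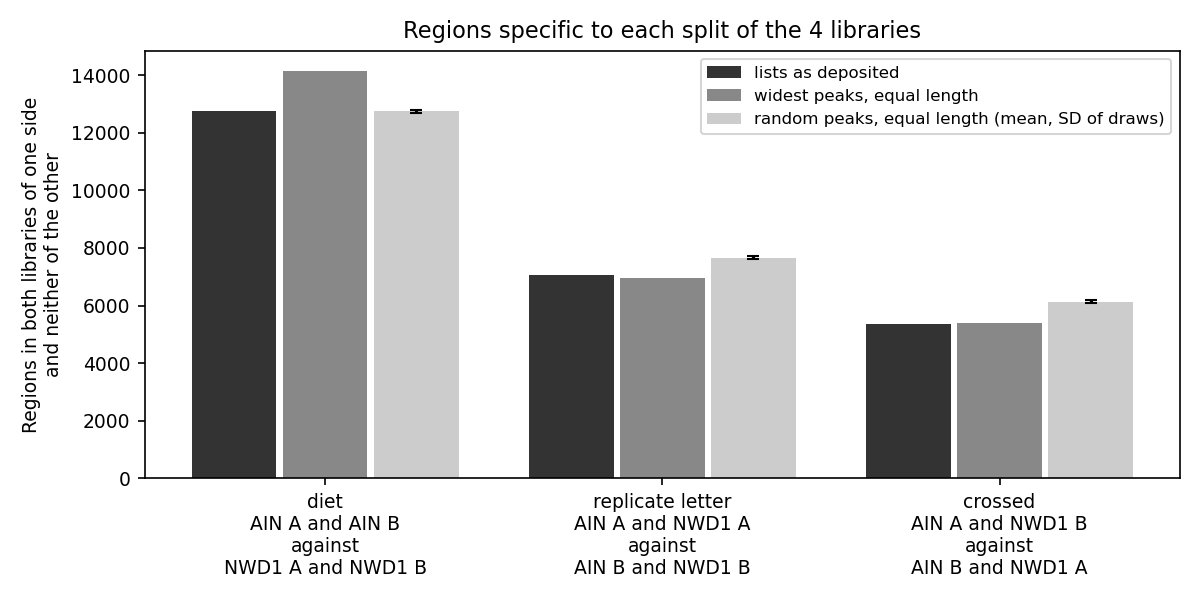
Number of union regions called in both libraries of a side and in neither of the other, for the 3 splits of the 4 libraries, with lists as deposited and with lists brought to equal length by width or at random (mean and SD of 100 draws). With lists as deposited the split by diet gave 12747 regions, the split by letter 7061 and the crossed split 5373, and with lists thinned at random these were 12755, 7666 and 6136.

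The third comparison asks which genes had a peak at either end in a single diet. A gene-end peak was called in all 4 libraries for 14689 of 21883 genes, in AIN only for 179 and in NWD1 only for 57. Trpv6, the apical calcium channel of the gut, had a gene-end peak in NWD1 only, whereas Axin2, a feedback target of Wnt signalling, the T cell kinase gene Lck, and Fdft1 of cholesterol synthesis had theirs in AIN only. The widest AIN-only peaks were at Syce1 (1125 bp, chromosome 7, 140787267 to 140788391), Efcab8 (1023 bp), Fam209 (996 bp), Gast, which encodes gastrin (991 bp, chromosome 11, 100333645 to 100334635), and Rnf17 (988 bp). The widest NWD1-only peaks were at Otx2, a homeobox transcription factor gene (1051 bp, chromosome 14, 48654822 to 48655872), Psg18 (1023 bp), Gm34768 (997 bp), Asic4 (991 bp) and Klri1 (991 bp). The split by letter gave 113 genes and the crossed split 92, against 236 by diet, and no fixed list passed between the AIN-only and NWD1-only genes (Fisher's exact test, smallest adjusted p = 1 over 29 lists). With at most 1 of these genes in any list, that test could not have passed a list (smallest unadjusted p = 0.242, for vitamin D and calcium). In lists of equal size 156 genes were NWD1-only and 163 AIN-only, and leaving out AIN A, AIN B, NWD1 A or NWD1 B gave 467, 592, 522 or 586 genes for the same reason as above.

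The fourth comparison is of the accessible length of 17705 genes. The median peak was 877 bp wide in AIN and 878 bp in NWD1, so many of the differences below amount to very few peaks. Where both libraries of a diet hold the same number of peaks, SD and SE cover peak width and not signal. Gbp7, an interferon-induced GTPase gene (chromosome 3, 142530336 to 142550151), had 854 ± 12.7 bp in AIN and 1848 ± 91.9 bp in NWD1 (SD, n = 2 each), a log2 difference of 1.08 ± 0.07 (SE). Idh3b, a subunit of isocitrate dehydrogenase, had 832 bp and 1728.5 bp (log2 1.02), and Lep, which encodes leptin, had 813.5 bp and 1799.5 bp. Lengths were also greater in NWD1 at Gm4450 (log2 1.76), Mei4 (1.48), Antxrl (810.5 bp and 1782 bp), Cd200r2 (1.07), Ntf5 (1.06), Adi1 of methionine salvage (1.02), Yipf2 (1.01), Zfp14 (830 bp and 1691 bp) and Dus3l (0.98). The keratin gene Krt82 (chromosome 15, 101541216 to 101550659) had 2179 ± 7.07 bp in AIN and 489 ± 5.66 bp in NWD1 (SD, n = 2 each), a log2 difference of -1.81 ± 0.06 (SE). Aox1, an aldehyde oxidase gene, had 3368.5 bp and 894.5 bp (log2 -1.69). Ankdd1a (log2 -1.76), Hmgb3 (-1.15) and Mss51 (-0.99) were also shorter in NWD1. No peak was listed in either NWD1 library at Muc5ac, a gastric mucin gene (1722 bp in AIN), Cdh2, which encodes N-cadherin (1743 bp), S100a8, a calprotectin subunit gene (1645.5 bp), Nsg1 (1793 bp), Galp (1722.5 bp) and 1300017J02Rik (1734.5 bp).

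None of these passed: limma called 0 of 17705 genes at an adjusted p under 0.05 (each gene above had adjusted p = 0.103), with 1502 at an unadjusted p under 0.05. Of these 1502, 601 were longer and 901 shorter in NWD1, against 836 genes for the split by letter and 652 for the crossed split. The median over all genes was 0.06, and 10755 genes (60.7%) were longer in NWD1. Both follow in part from the scaling, since the AIN lists cover more and a gene of equal length is then longer in NWD1. Without scaling, 7311 genes (41.3%) were longer and the median was -0.02. The diets did not overlap in 9005 genes (50.9%) with scaling (6735 longer in NWD1) and in 7167 (40.5%) without (2667 longer). By chance 33.3% of genes would separate 2 libraries from the other 2. With scaling, the split by letter separated 4445 genes and the crossed split 4255. The count that passed was 429 without scaling by covered length, 331 in lists of equal size, 124 with plain limma, 94 with a pseudocount of 10, 70 with no filter, 12 without NWD1 A and 184 without NWD1 B. The unadjusted split into longer and shorter genes was 501 and 1354 without scaling and 958 and 856 in lists of equal size, so the balance between the directions depends on how list length is treated.

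Genes of intestinal stem cells and targets of Wnt signalling, which maintains those cells, were mostly shorter in NWD1. Of 17 Wnt targets, 13 were shorter and 4 longer (median log2 -0.11), and of 13 stem cell genes 9 were shorter and 4 longer (median -0.12). Against the median of all genes, 14 Wnt targets lay below and 3 above, and 10 stem cell genes below and 3 above. Axin2 had 6789 ± 140 bp in AIN and 4743 ± 655 bp in NWD1 (SD, n = 2 each), a log2 difference of -0.43 ± 0.13 (SE). The cell cycle gene Ccnd1 differed by -0.58, the stem cell transcription factor gene Ascl2 by -0.26 and Smoc2 by -0.15. Lgr5, the receptor gene that marks crypt base stem cells (chromosome 10, 115450314 to 115587780), had 9734.5 ± 609 bp and 7859 ± 774 bp (SD, n = 2 each), a log2 difference of -0.22 ± 0.12 (SE). Olfm4 differed by -0.12, and the ranges of its diets overlapped. In lists of equal size Ascl2 turned to 0.32, and without AIN B Olfm4 turned to 0.02. By camera, Wnt targets had adjusted p = 0.149 and stem cell genes 0.283 (unadjusted p = 0.00513 and 0.0195), and with an estimated correlation the adjusted p was 0.937 for both. By fry, which tests whether genes move on balance one way, the adjusted p was 0.207 and 0.328. Axin2, Lgr5, Ascl2, Sox9, Cd44, Ephb2 and Tnfrsf19 stand in both lists.

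The reserve stem cell gene Bmi1, a Polycomb component, had 738 ± 17.0 bp in AIN and 685.5 ± 16.3 bp in NWD1 (SD, n = 2 each), a log2 difference of -0.02 ± 0.08 (SE) that was 0.35 after quantile normalization and 0.38 at gene ends with 10 kb. Of the 11 reserve and regenerative stem genes 6 were shorter and 5 longer, among them the telomerase gene Tert (-0.31), Ly6a (-0.66) and Mex3a (0.80), with camera adjusted p = 0.778. Of the 12 genes of cycling progenitors 6 were longer and 6 shorter (adjusted p = 0.892), including Ccna2, which encodes cyclin A2 (-0.81), Top2a (-0.67) and Tyms (0.29). Their median was 0.02 but their mean -0.08, and camera's direction was down.

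Genes of fat uptake lay near the median of all genes. Of 20 lipid absorption and chylomicron genes 18 were longer in NWD1 and 2 shorter, but 12 lay above the median of all genes and 8 below (median log2 0.09, camera adjusted p = 0.327, and adjusted p = 0.937 with an estimated correlation). Apob, the structural protein of chylomicrons, had 4235.5 ± 1036 bp in AIN and 6152.5 ± 1541 bp in NWD1 (SD, n = 2 each), a log2 difference of 0.61 ± 0.30 (SE). The fatty acid transporter gene Cd36 differed by 0.40 and the lipoprotein receptor gene Scarb1 by 0.26. Of 24 genes of fatty acid oxidation and PPAR targets 19 were longer and 5 shorter (15 above the median of all genes, adjusted p = 0.662), among them Hadha (0.51) of beta oxidation and Ppargc1a (-0.16). The TCA cycle and oxidative phosphorylation list had 11 longer and 6 shorter (0.778), with Idh3a at 0.34, Idh2 at 0.25 and Cox5a at 0.24. In cholesterol synthesis 11 were longer and 7 shorter (0.778), with Insig1, a brake on sterol synthesis, at 0.71 and Fdft1 at -0.19. Enterocyte genes had 14 longer and 8 shorter (0.778, and adjusted p = 0.937 with an estimated correlation), with Slc2a5, the fructose transporter gene, at 0.31 and Apoa4 at 0.33. Carbohydrate digestion and uptake had 7 longer and 6 shorter (0.886), with Mgam at 0.36 and G6pc at 0.16. Without AIN B the enterocyte and lipid absorption lists passed, both up with adjusted p = 0.0207, and without AIN A the enterocyte list turned down (0.512).

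The vitamin D and calcium list stood out for Trpv6 (chromosome 6, 41620619 to 41636405), with no peak listed in either AIN library and 2696 bp in NWD1 A and 1325 bp in NWD1 B (adjusted p = 0.118 from limma). S100g, a cytosolic calcium-binding protein gene of enterocytes, had 1365 ± 680 bp in AIN and 2476.5 ± 301 bp in NWD1 (SD, n = 2 each), a log2 difference of 0.95 ± 0.37 (SE); it lies outside the naming rule and was chosen after its values were seen. Slc30a10, a manganese exporter gene, differed by 0.48 ± 0.11 (SE). Cyp24a1, which inactivates vitamin D, had 2428.5 ± 68.6 bp in AIN and 1793.5 ± 61.5 bp in NWD1 (SD, n = 2 each), a log2 difference of -0.33 ± 0.09 (SE), and the vitamin D receptor gene Vdr had 12718.5 ± 415 bp and 10525 ± 124 bp, a difference of -0.18 ± 0.07 (SE). In all 10 of the 14 genes were longer and 4 shorter, with a camera adjusted p of 0.778. fry's mixed test, of change in either direction, gave this list an adjusted p of 0.0071. The same test called 8 of the 29 lists, T cell and B cell among them, and does not compare a list with other genes. The highest log2 difference in the list, 3.94, was that of Trpv6 and depends on the pseudocount, against a list median of 0.08.

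Other metabolic and immune lists held members on both sides. In one-carbon metabolism and DNA methylation 14 genes were longer and 8 shorter (camera adjusted p = 0.778), with the serine hydroxymethyltransferase genes Shmt1 at 0.78 and Shmt2 at 0.55, and Tet2, a DNA demethylation enzyme gene, at 0.35. In bile acid handling 6 were longer and 2 shorter (0.778), with the export pump gene Abcc3 at 0.38 ± 0.06 (SE), Abcc2 at -0.28 and Nr1h4 at 0.22. The MHC class II and interferon list had 12 longer and 5 shorter (0.778), with Gbp7 at 1.08 and H2-DMb1, a chaperone gene of MHC class II, at -0.72. The inflammation and antimicrobial list had 12 longer and 4 shorter (0.662), with Reg3a at 0.43, Saa1 at 0.12 and Nos2 at -0.23. Intestinal transcription factor genes had 9 longer and 9 shorter (0.892), with Hnf4a, a regulator of enterocyte genes, at 0.26 ± 0.16 (SE), Gata4 at 0.37, Gata5 at 0.29 and Elf3 at -0.21. At gene ends with 10 kb Tet2 was at -0.29, Gata4 at -0.07 and G6pc at -0.06.

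The fixed lists of secretory lineages showed no common direction. Goblet cell genes had 8 longer and 4 shorter (camera adjusted p = 0.778), with Zg16 at 0.42, Clca1 at 0.36 and Galnt12 at -0.34. Paneth cell genes had 3 longer and 3 shorter of 6 measured (0.778), with Habp2 at -0.63, Ang4 at 0.44 and Mmp7 at -0.38, the last turning to 0.02 without AIN A. Enteroendocrine genes had 8 longer and 8 shorter (0.778), with Isl1, a transcription factor gene of hormone-producing cells, at -0.88 ± 0.07 (SE), and Pax6 at 0.31. Tuft cell genes had 7 longer and 6 shorter (0.917), with Ptgs1 at -0.67, Il17rb at 0.24 and Trpm5 at 0.18. Their median was 0.09 and their mean -0.01, and camera's direction was down while fry's was up.

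Markers of cells that the sort should remove were also measured. T cell genes had 6 longer and 3 shorter of 9 measured (camera adjusted p = 0.917, median 0.04, mean -0.02, direction up), with Zap70 at 0.75, Lck at -0.66 and Ikzf3 at -0.98. B cell genes had 4 longer and 2 shorter (0.892, median 0.05, mean -0.02, direction down), with Cd22 at -0.65, Pax5 at -0.56, which was 0.09 at gene ends with 10 kb, and Pou2af1 at 0.50. Myeloid genes had 5 longer and 4 shorter (0.778, median 0.08, mean -0.01, direction down), with Csf1r at -0.56, Itgax at -0.63 and Lyz2 at 1.23. Fibroblast genes had 2 longer and 5 shorter (0.535), with Col3a1 at -1.87, Twist1 at -1.55 and Pdgfra at -0.25. Endothelial genes had 5 longer and 3 shorter (0.886), with Tie1 at 0.75, Pecam1 at 0.19 and Erg at -0.21. Smooth muscle genes had 4 longer and 2 shorter (0.917), with Actg2 at -0.27, Des at 0.11 and Tagln at 0.09. Enteric glia and neuron genes had 4 longer and 2 shorter (0.778, median 0.09, mean -0.03, direction up), with S100b at 0.34 and Tubb3 at 0.13. Housekeeping genes had 10 longer and 5 shorter (0.778), with Hprt at -0.61 and Hsp90ab1 at 0.30. Genes of other tissues had 13 longer and 2 shorter (9 above the median of all genes, 0.327, and adjusted p = 0.937 with an estimated correlation), with Snap25 at 0.33, Amhr2 at 0.26 and Syt1 at 0.21.

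Over all 29 lists camera called 0 at an adjusted p under 0.05, with 4 at an unadjusted p under 0.05 and 0 adjusted with an estimated correlation. fry called 0 lists for change one way. Its mixed test, which asks whether genes change in either direction, called 8: bile acid handling (adjusted p = 9.02e-06), enteroendocrine (0.00623), vitamin D and calcium (0.0071), MHC class II and interferon (0.0071), cholesterol synthesis (0.0205), T cell (0.0267), B cell (0.0267) and cycling progenitor (0.0414). Neither fry test compares a list with other genes. Adjusted over the list alone, 8 genes passed (Trpv6, Gbp7, H2-DMb1, Insig1, Isl1, Ccna2, Zap70 and Cd22), against 0 over all genes tested and 0 over the 361 list genes together.

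**Figure D3:**
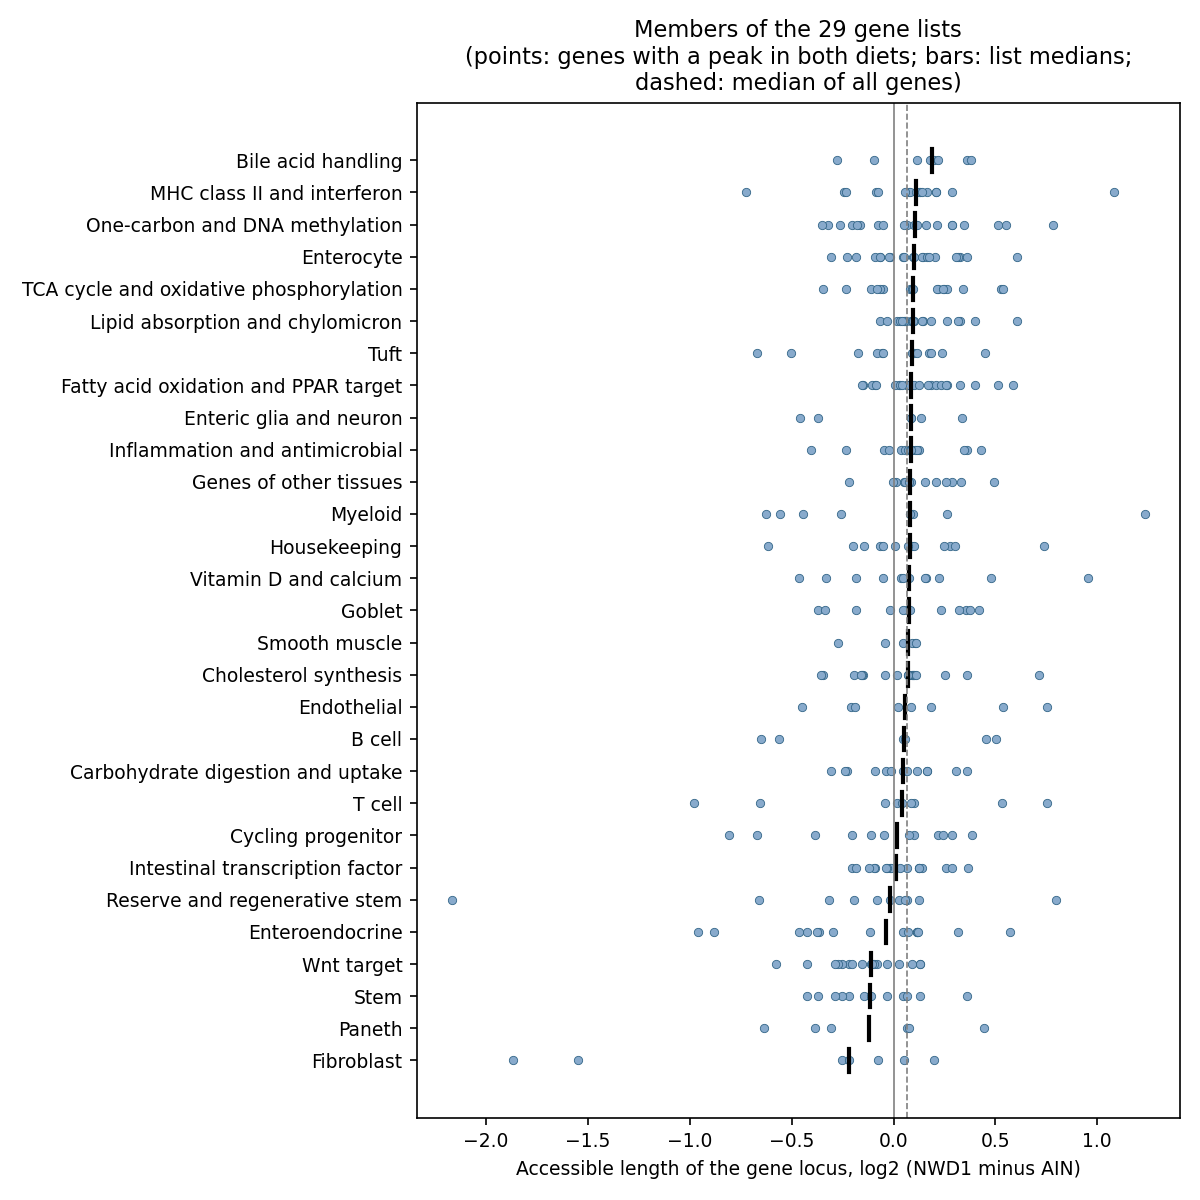
Log2 difference in accessible length (NWD1 minus AIN) of genes with a peak in both diets in the 29 fixed lists (points), with the median of each list (bars) and of all genes (dashed line). Wnt targets have a median of -0.11 and stem cell genes of -0.12, and lipid absorption genes of 0.09.

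Diet-specific regions in the loci of the fixed lists were counted as a comparison chosen after the data had been seen. Genome-wide, 8684 regions were AIN-only and 4063 NWD1-only. Wnt target loci held 19 AIN-only and 3 NWD1-only regions, the latter inside Cd44, Ephb2 and Znrf3. Loci of stem cell genes, a list that shares members with the Wnt targets, held 12 and 4 (odds ratio 1.4, Fisher's exact unadjusted p = 0.789). The AIN-only regions included chromosome 11, 108917247 to 108918187, at the end of Axin2, and chromosome 10, 115478248 to 115479164, inside Lgr5. Another lay at chromosome 7, 142967995 to 142968563, inside Ascl2. Lipid absorption loci held 2 AIN-only and 5 NWD1-only regions, among the latter chromosome 5, 17879543 to 17880356, inside Cd36 and chromosome 12, 8011908 to 8012793, inside Apob. TCA cycle loci held 0 and 3, with chromosome 6, 73252468 to 73252963, inside Suclg1. Fatty acid oxidation loci held 8 and 9, vitamin D and calcium loci 3 and 5, and endothelial loci 1 and 4. The latter vitamin D regions included chromosome 6, 41635949 to 41636818, at the end of Trpv6, chromosome 6, 41637883 to 41638818, in its flank, and chromosome 1, 185466558 to 185467541, inside Slc30a10. No list passed by Fisher's exact test (smallest adjusted p = 0.371, for the TCA cycle, lipid absorption and endothelial lists), and Wnt targets had adjusted p = 0.412.

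Nuclei of NWD1 A were grouped by cell type, which bears only on peaks called in that library. Of 9379 barcodes, 8884 were kept with a median of 6457 counts, and they formed 12 clusters, 7 of them named. Enterocyte-like nuclei, in 3 clusters with 1.68-fold, 1.76-fold and 1.75-fold signal at the fatty acid binding protein gene Fabp1, numbered 3534 (39.8%, interval 38.8 to 40.8%). The stem-like cluster held 1521 nuclei (17.1%, 16.3 to 17.9%), with fold signal over the other nuclei of 3.06 at Lgr5, 3.80 at Olfm4 and 4.53 at Ascl2. Goblet-like nuclei numbered 648 (7.29%, 6.76 to 7.85%), with 15.8-fold signal at the mucin gene Muc2 and 23.5-fold at Zg16. Tuft-like nuclei numbered 178 (2.00%, 1.72 to 2.32%), with 72.9-fold signal at Chat, the acetylcholine synthesis gene, and 17.8-fold at Gfi1b. Enteroendocrine-like nuclei numbered 175 (1.97%, 1.69 to 2.28%), with 40.8-fold signal at Neurod1.

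Further genes of highest fold were Kif12 (5.28-fold) and Zfp957 (14.4-fold) in the stem-like cluster, and Trpv5, Slc28a2 and Cyp7a1 in enterocyte-like cluster 1. Trpv6 headed enterocyte-like cluster 2 (5.75-fold) and was 3.63-fold higher in cluster 1, and S100g was 2.34-fold and 2.79-fold higher there. The lactase gene Lct marked enterocyte-like cluster 5 (4.30-fold). Bmi1 signal was 0.859-fold in stem-like, 0.822-fold in goblet-like, 1.04-fold in tuft-like and 1.45-fold in enteroendocrine-like nuclei, the last from 28 counts. Ascl2 was highest per count in tuft-like nuclei (0.759 per 10000 counts, against 0.511 in the stem-like cluster). Of the 5 unnamed clusters, cluster 3 (1367 nuclei, 15.4%) had high signal at the mucin gene Muc3a (3.24-fold) and at Reg3b (3.08-fold), an antimicrobial lectin gene. Cluster 4 (823 nuclei, 9.26%) had high signal at Ly6m (10.5-fold), the carboxylesterase gene Ces1c and the monocarboxylate transporter gene Slc5a8 (7.05-fold). Clusters 7, 8 and 11 held 377, 235 and 26 nuclei. Doublets were not removed. At Leiden resolution 0.4 no cluster took the stem-like name, and under the other settings the stem-like share ranged from 10.9% to 18.5%. The enterocyte-like share ranged from 24.3% to 44.9%, and with nuclei of at least 3000 counts no cluster took the enteroendocrine-like name. With gene-end peaks, 4 of the 7 names were kept.

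**Figure D4:**
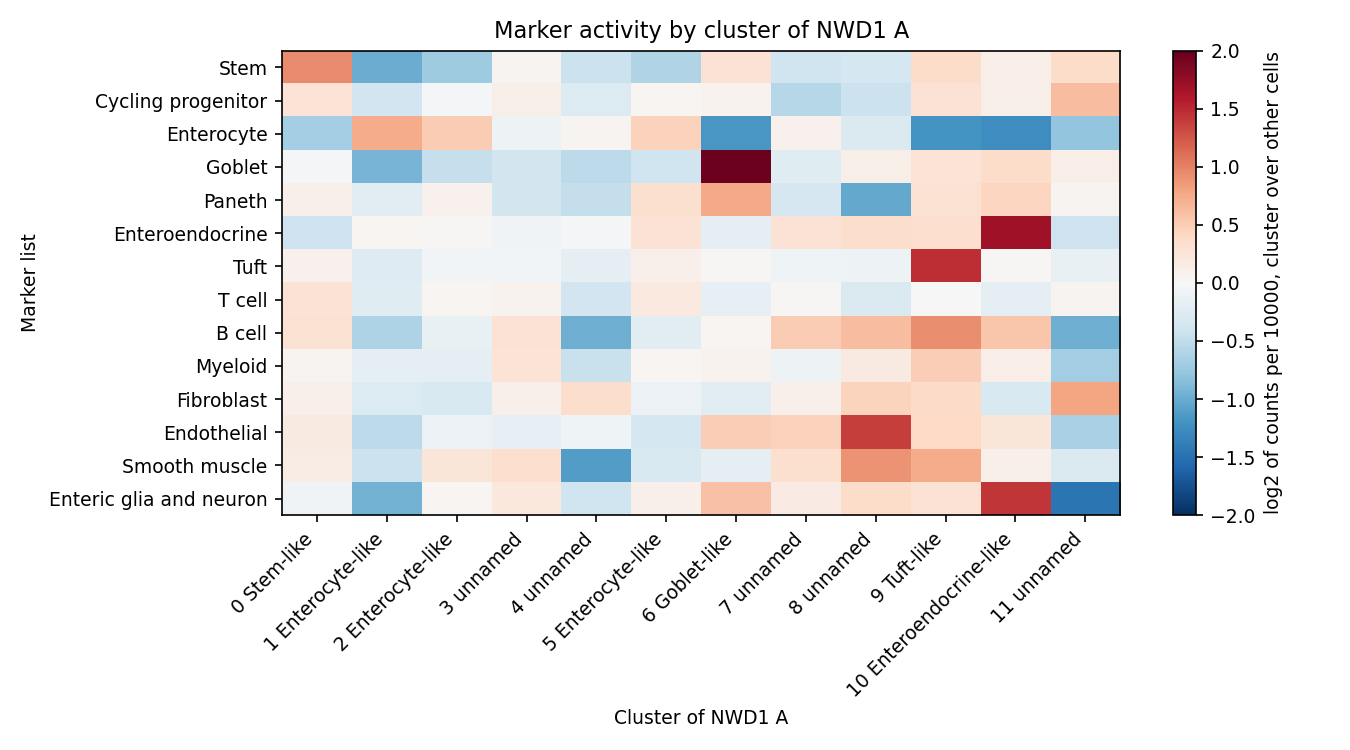
Log2 of the counts per 10000 of each cell type marker list (rows) in each cluster of NWD1 A (columns), over those of the other nuclei. The stem cell list is 1.92-fold in the stem-like cluster and the goblet list 3.88-fold in the goblet-like cluster.

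Counts at NWD1-only regions were then divided by cluster, beside regions called in all 4 libraries with a matched number of counts. Enterocyte-like nuclei gave 35.4% of the 328077 counts in NWD1-only regions and 24.9% ± 0.402 (SD, 100 draws) in matched regions, a difference of 10.5 percentage points. Stem-like nuclei gave 12.2% and 24.6% ± 0.328, a difference of -12.4 points, and goblet-like nuclei 5.85% and 10.1%. Tuft-like nuclei gave 1.503% and 2.67%, and enteroendocrine-like nuclei 1.72% and 2.69%. Of the unnamed clusters, cluster 3 gave 13.2% and 22.0%, cluster 4 gave 15.7% and 7.16%, and cluster 8 gave 9.81% and 2.19%. The first region at Trpv6 drew 85.0% of its 127 counts, and the flanking region 85.7% of its 251 counts, from enterocyte-like nuclei. Against all regions of the 4 lists, unmatched in counts, the differences were 1.80 points for enterocyte-like, -9.63 for stem-like, -2.34 for goblet-like, -0.270 for tuft-like and 0.0185 for enteroendocrine-like nuclei, so the last turned. Regions missing from AIN A alone drew still more from enterocyte-like (43.5%) and less from stem-like nuclei (9.66%) than NWD1-only regions did. These sets were not matched in counts, with medians of 89 and 55 counts. Regions missing from AIN B alone drew 24.7% and 18.96%, and those called in AIN B and NWD1 A only drew 31.3% and 19.2%. Those called in NWD1 A alone (median 41 counts) drew 25.6% and 15.2%. Those called in AIN A and NWD1 A only (median 48) drew 19.97% and 19.47%, and those missing from NWD1 B alone 22.6% and 26.9%. A stem-like share below that of the matched regions was thus not particular to NWD1-only regions, though these other sets were not matched in counts.

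As a comparison added after the data had been seen, regions enriched in a cluster of NWD1 A were looked up in the other lists. Enriched means at least 20 counts in the cluster and over 2 times the share of counts found in the other nuclei. Such a region can still draw most of its counts from other clusters, and can pass for several. Regions of the stem-like cluster were called for 98.0% in AIN A, 96.2% in AIN B and 92.0% in NWD1 B, and those of the unnamed cluster 3 for 96.9%, 95.6% and 91.0%. Those of cluster 4 were called for 78.1% in AIN A, 92.9% in AIN B and 97.7% in NWD1 B, and those of enterocyte-like cluster 1 for 85.1%, 92.9% and 95.4%. Goblet-like regions were called for 97.7%, 96.2% and 94.5%, tuft-like for 97.3%, 97.4% and 96.9%, and enteroendocrine-like for 97.3%, 96.9% and 97.3%. Regions of cluster 8, with a median of 56 counts, were called for 58.2%, 29.8% and 52.2%, and 835 of them (11.1%) were NWD1-only. For those with at least 100 counts the values were 95.3%, 94.5% and 96.2%, with 20 NWD1-only (1.28%). At that limit stem-like regions were called for 99.4%, 99.1% and 97.9%. Only regions called in NWD1 A can enter this comparison. With no limit on counts, AIN A had the lowest values in clusters 1, 2, 4, 5, 7 and 11 (in the last, 99.7% against 99.8% in AIN B and NWD1 B).

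**Figure D5:**
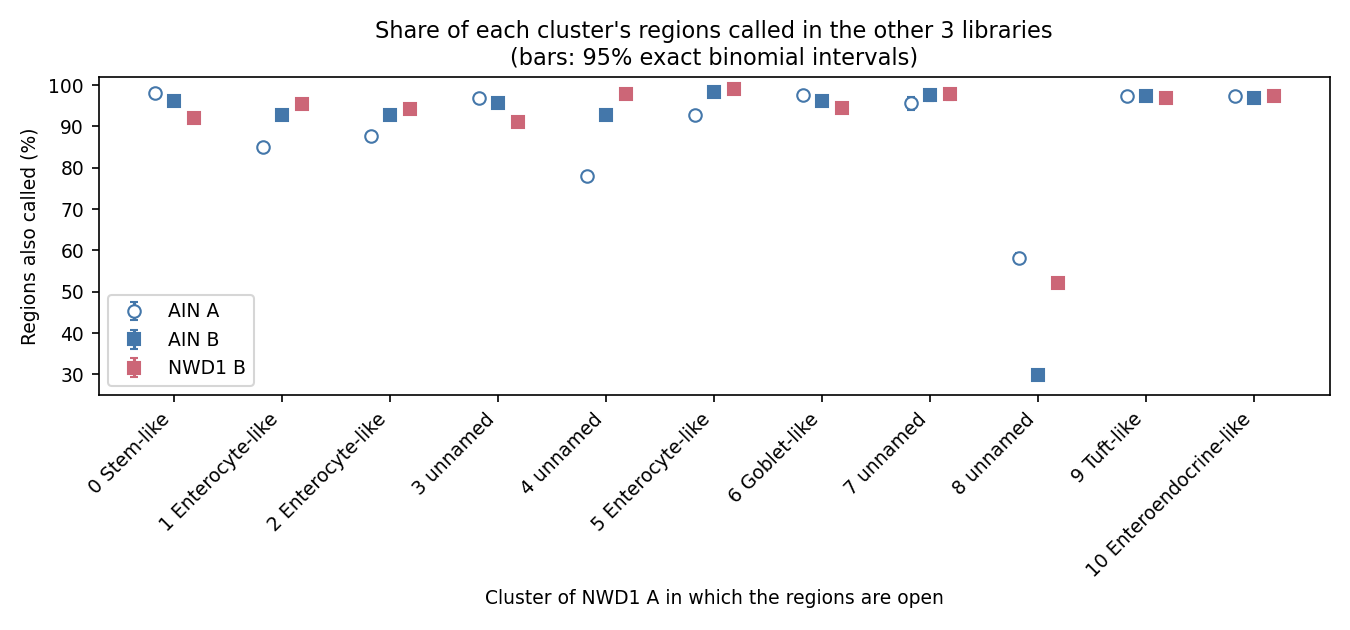
Percent of the regions enriched over 2-fold in each cluster of NWD1 A, cluster 11 left out, that were also called in AIN A, AIN B and NWD1 B, with exact 95% intervals and an axis that does not start at 0. Stem-like regions were called for 98.0%, 96.2% and 92.0%, and regions of cluster 4 for 78.1%, 92.9% and 97.7%.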

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

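Of 1701 alternatives, 1505 kept direction and side of the threshold, or the value within its bound, 53 moved, 113 came to pass, 0 ceased to pass and 30 reversed, 16 of these with a library left out. No gene or fixed list passed in the main analysis, so none could cease to pass, and the 1505 include results that passed neither way. Random thinning of the lists was added after the data had been seen; the other alternatives were planned. Among 110 named genes, 33 came to pass under some alternative and 9 reversed. Except where a sentence gives it, the cause was not tested.

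Equal-size lists gave 6753 NWD1-only regions, 156 genes with an NWD1-only end peak and 331 genes passing, and reversed Hmgb3 (0.00487) and Ascl2 (0.32). Genes passing numbered 94 with a pseudocount of 10, 70 with no filter, 429 with no scaling and 124 with plain limma. Gene ends with 10 kb reversed Pax5 (0.0887), Tet2 (-0.29), G6pc (-0.0600), Gata4 (-0.0704) and Bmi1 (0.38), and quantile normalization reversed Bmi1 (0.35). They also turned the B cell list up (adjusted p = 0.924) and the one-carbon, carbohydrate (0.924 each) and cholesterol lists (0.951) down. No scaling turned cycling progenitor up (0.962). Gene-end peaks kept 4 of 7 cluster names. Unmatched regions gave 1.80 points for enterocyte-like and -9.63 for stem-like counts, and 50% cover gave -12.3 for stem-like counts.

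With replicate letter as a block, which shares only a name between 2 pairs, limma called 0 genes (smallest adjusted p = 0.152) and camera 0 lists, and the T cell list turned down (0.948). The count of 12747 diet-specific regions is the same with this block by construction, so it tests nothing. Deviations of the letters correlated across genes at 0.113 (Pearson) and 0.0428 (Spearman); genes are not independent replicates.

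Leaving out 1 library in turn, where a lone library is assumed to vary like the other diet, gave these ranges. The Jaccard index within diets exceeded that across diets by 0.00972 (without AIN A) to 0.0424. Requiring a peak in only 1 library of a diet raises region counts by construction: 25886 to 34085 diet-specific regions (14550 to 24775 AIN-only, 7956 to 13658 NWD1-only) and 467 to 592 genes with diet-specific end peaks (305 to 476 AIN-only, 116 to 190 NWD1-only). Genes passing ranged from 0 to 184 and lists from 0 to 2. Log2 differences ranged from -0.789 to 0.0212 for Mmp7, -0.0499 to 0.0173 for Bmi1 and -0.253 to 0.0207 for Olfm4. For lists that turned, adjusted p ranged from 0.739 to 0.997 for cycling progenitor, 0.0207 to 0.712 for enterocyte, 0.545 to 0.997 for Paneth, 0.488 to 0.997 for enteroendocrine, 0.645 to 0.997 for tuft, 0.714 to 0.997 for T cell, 0.791 to 0.997 for B cell, 0.683 to 0.997 for endothelial, 0.712 to 0.997 for smooth muscle and enteric glia, and 0.484 to 0.997 for carbohydrate and for intestinal transcription factor.

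Whether depth limits the calls was not tested: an NWD1-only region had a median of 55 counts in NWD1 A, against 235 for regions of all 4 lists. The motif comparison and its alternatives were not run.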

Other observations

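Of the tests in this part, the Trpv6 tests were set before their values were seen, and the tests on cluster gene sets, neighbouring regions, list length, AIN A, regions near the calling limit in the cluster comparison (alone and with AIN A) and diet-specific chromatin were chosen after the result was seen.

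The 200 leading genes of each cluster of NWD1 A were compared between diets by accessible length. Genes of enterocyte-like cluster 1 were longer in NWD1 (129 above and 71 below the median of all genes, median log2 0.09, camera adjusted p = 0.0236), and this call was lost with an estimated correlation (adjusted p = 0.958) and without AIN A (0.439). Enterocyte-like clusters 2 and 5 did not pass (113 above and 87 below, adjusted p = 0.260, and 118 and 82, 0.121). Without NWD1 A, the library that defined the clusters, the adjusted p of cluster 1 was 0.0181. Genes of cluster 4, led by Ly6m and Slc5a8, had 127 above and 73 below (median 0.12, camera adjusted p = 0.0668, and 0.958 with an estimated correlation). They stayed up without NWD1 A and without AIN A. Tuft-like genes, led by Chat and Alox5ap, had 70 above and 130 below (median -0.05, 0.0668), goblet-like genes 76 and 124 (-0.03, 0.121), stem-like genes 79 and 121 (0.03, 0.225), and enteroendocrine-like genes 91 and 109 (0.03, 0.851). Genes of cluster 8, led by the neuronal adhesion genes Nlgn1 and Ncam1 and by Nrg1, had 123 above and 77 below (median 0.17). Their camera adjusted p was 0.0837, and 0.958 with an estimated correlation. They stayed up without AIN A and turned down without NWD1 A.

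Regions called in all 4 libraries within 50 kb of a diet-specific region also differed in the clusters that opened them. In NWD1 A, stem-like nuclei gave 22.3% of counts near AIN-only and 20.7% near NWD1-only regions, a difference of 1.55 ± 0.190 points (SE over 21 chromosomes). Enterocyte-like nuclei gave 33.1% and 35.5%, a difference of -2.32 ± 0.245 points. The split by letter gave 1.34 ± 0.180 and -1.86 ± 0.271 points, and the crossed split 0.989 ± 0.221 and -1.75 ± 0.297 points. In each split a pair with AIN A was set against a pair without it. Pairs with AIN A had stem-like shares of 22.3%, 22.3% and 22.1%, and the others 20.7%, 20.9% and 21.1%. Enterocyte-like shares were 33.1%, 33.2% and 33.3% against 35.5%, 35.1% and 35.1%. The differences thus follow AIN A as well as diet.

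The split by diet had the most regions called on 1 side alone, 12747 against 7061 for the split by letter, with 8684 for the AIN pair, 4063 for the NWD1 pair and 4078 for AIN A with NWD1 A, and in lists of equal size 7393, 6753 and 3739. That AIN A stands apart could give such a pattern and stays open: without AIN A the NWD1 pair had 1.36 times the 2983 regions of the next pair, AIN B with NWD1 B, but its Jaccard index was no higher (0.699 for both). Longer AIN lists could also give it. With lists thinned at random to equal length the ratio of the diet split to the next was 1.66, and 2.04 by width. The lists hold no score, so neither way is known to drop the weakest peaks, and list length stays open. With 3 splits, a grouping by chance cannot be tested below a share of 0.05. Diet therefore stays a hypothesis, beside any other difference between the samples of the diets.

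Regions of the stem-like cluster and of cluster 3 were called less often (-5.14 and -5.21 points against the AIN mean, and -1.32 and -1.62 for regions of at least 100 counts), and those of cluster 4 more often, in NWD1 B than in the AIN lists. Shorter NWD1 lists could give the first part, but NWD1 B called 4.85 points more of the cluster 4 regions than AIN B did, which a shorter list alone would not give. The gap between the clusters, NWD1 B minus AIN, was 9.07 points against AIN B (25.7 against AIN A), so AIN A alone could not account for all of it. For regions of at least 100 counts the gap was 9.05 points against the AIN mean (17.4 over all regions). These are counts in NWD1 A, so such a region can still lie near the calling limit of another list. The calling limit therefore stays open. With both, against AIN B and at 100 counts or more, the gap was 3.39 points. In log odds, which have no ceiling, 0.944 of the gap was left at 100 counts or more and 0.668 against AIN B. With both, 0.631 was left (1.87 ± 0.137, counting SE, of 2.97). The 2 scales differ, so what part they give together stays open. The stem-like difference near diet-specific regions exceeded that of the next split by 0.207 ± 0.262 points. In every split the side with AIN A had the higher stem-like share, so this test cannot separate diet from AIN A. A change of chromatin specific to diet therefore stays open and is not shown. Diets that differ in the share of each cell type cannot be told apart from diets that differ within a type. Matrices of AIN nuclei were not analysed here.

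Trpv6, whose product takes up dietary calcium, had peaks in both NWD1 lists and in neither AIN list, and 85.7% of the 251 counts at its flanking region came from enterocyte-like nuclei. A calling limit could leave out such a region: of 16001 NWD1 A regions with a like number of counts, 147 were missing from both AIN lists, or 0.919% (exact interval 0.777 to 1.08%), which spans the bound of 1% set beforehand. Fewer enterocyte-like nuclei in the AIN libraries could too: of 44 regions that also drew as much from those nuclei, 2 were NWD1-only, or 4.55% (0.555 to 15.5%). The intervals were brought in after the values were seen, and a first run that counted the tested region itself gave 0.925% and 6.67%. Both explanations, and a response of the gene to the low calcium and vitamin D of NWD1, cannot be told apart here.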
